A study of Homo sapiens with 12 samples.

How the data were processed

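Total RNA of A375, an established human malignant melanoma line, was sequenced in 12 libraries after ribosomal RNA removal. Per the labels, the cells received A771726 at 25 µM or the vehicle DMSO. A771726 is the active metabolite of leflunomide and inhibits dihydroorotate dehydrogenase, an enzyme of pyrimidine synthesis. Groups were taken from the sample titles, which place 2 libraries in each of 6 groups. The titles give treatment times from 0 to 72 h, whereas the extraction protocol in the labels gives a single time of 48 h, and the titles were followed. The labels do not say whether the libraries of a group came from separate cultures.

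The authors' deposited table holds 1 line per RefSeq transcript model, with gene symbol, transcript identifier, chromosome, start, end and strand, followed by 12 columns of expression values. Per the submitters' processing notes, cutadapt, TopHat2 2.0.11, Cufflinks 2.2.1 and the genome build hg19 were used. The deposited values are FPKM estimates by Cufflinks according to the table's own name. The filters, the annotation release and the strand setting are not given in the sources used here.

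The 12 value columns carry serial names that occur in 0 of the sample labels, so none of them was given a sample or a group. Their order in the table was not taken as evidence of a group, and a grouping by the level of any gene would have built the outcome into it. All 12 were therefore left out of every step, and no expression level, depth, fold change or p-value was computed. The limma tests that had been fixed before the data were examined were not run. They compared each treatment time with 0 h and with the time before it. They also compared 72 h of A771726 with 72 h of DMSO, and 72 h of DMSO with 0 h. A planned F test over the A771726 times was not run. The same holds for a planned comparison, beside simulated groups, of the changes from 0 h to 72 h under A771726 and DMSO. Other settings listed in advance (pseudocount, filters, scaling, replicate block and omission of each library) and the gene list tests were not run either. The plan had also assumed 1 value per gene, whereas the table lists transcript models.

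The identifier and position columns were read with pandas 2.3.3 in Python 3.11.15. Transcript models were counted as lines of the table, but per gene symbol as different transcript identifiers. The span of a model was taken as its end minus its start plus 1 base. Gene lists fixed before the data were examined were matched to the symbols of the table, with an older or newer symbol accepted where a list entry gave one. Positions are those of the table on hg19. Models on haplotype or unplaced sequences were left out of the positions and model counts given for single genes. The reference annotation at hand is on GRCh38 and was not used. The rule for naming genes needed expression values; the genes whose positions are given below comprise those that it always named (HEXIM1, CDKN1A, MDM2, DHODH, MYC and MITF) and others chosen later from the lists on P-TEFb and pyrimidine synthesis (CDK9, CCNT1, LARP7, CAD and UMPS).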

Results

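The series measured RNA abundance in A375 melanoma cells over a time course of A771726 treatment. Cells were treated with 25 µM A771726 for 0, 12, 24, 48 or 72 h, and a vehicle group received DMSO for 72 h. The 0 h group is labelled as A771726 but had no time under the drug. Its titles do not name DMSO, so a comparison with 0 h could also include an effect of the vehicle. Each of the 6 groups held 2 libraries, for 12 libraries in all. The vehicle was sampled at 72 h only, so 72 h was the single time at which drug and vehicle could be set side by side after equal treatment. Later times could otherwise be compared with 0 h. The titles do not say when the cells were plated or collected. If they were collected at successive times, drug effect and time in culture change together.

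The series title names HEXIM1 and nucleotide stress, and the design allows the question of how transcript levels move under A771726, an inhibitor of pyrimidine synthesis. The 12 value columns of the expression table could not be tied to these groups, because their names occur in 0 of the sample labels. Expression values were therefore not analysed here, and no comparison between groups or between libraries was made. What follows describes the genes and transcript models that the table listed.

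The table listed 43497 RefSeq transcript models, counted as lines, under 23615 gene symbols. Of these models, 35939 had coding (NM) identifiers and 7558 had noncoding (NR) identifiers. Counted instead by different transcript identifiers, 15219 symbols had a single model and 8396 symbols had more than 1. The genomic span, introns included, was under 300 bp for 1804 models. The plan took 300 bp as the fragment size selected for sequencing and would have left out genes with shorter loci. Alternate haplotype or unplaced sequences of the assembly carried 2273 models, and models there are not counted for the single genes described below.

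HEXIM1, an inhibitor of the transcription elongation factor P-TEFb, was represented by 1 model on the plus strand of chromosome 17 (hg19, start 43224684, end 43229468). The P-TEFb kinase CDK9 had 1 model on chromosome 9 (start 130548305, end 130553052, plus strand). Its partner CCNT1, which encodes cyclin T1, had 1 model on chromosome 12 (start 49082241, end 49110781, minus strand). LARP7, a protein of the 7SK ribonucleoprotein that holds P-TEFb inactive, had 4 models on chromosome 4 (start 113558120, end 113578748, plus strand). Of the 21 entries in the list for HEXIM1, 7SK and P-TEFb, 20 were found in the table, and the 7SK RNA gene RN7SK was not matched.

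The enzymes of de novo pyrimidine synthesis were all represented. CAD, which carries out the first steps of the pathway, had 1 model on chromosome 2 (start 27440258, end 27466654, plus strand). DHODH, the target of A771726, had 1 model on chromosome 16 (start 72042643, end 72059316, plus strand). UMPS, which forms uridine monophosphate, had 3 models on chromosome 3 (start 124449213, end 124468119, plus strand). All 22 entries of the list for pyrimidine synthesis and salvage and all 18 of the list for purine synthesis and salvage were matched.

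Among genes of growth control, the p53 target CDKN1A had 4 models on chromosome 6 (start 36644237, end 36655116, plus strand). MDM2, the p53 ubiquitin ligase, had 1 model on chromosome 12 (start 69201971, end 69239320, plus strand). The transcription factor gene MYC had 1 model on chromosome 8 (start 128748315, end 128753680, plus strand). The melanocyte lineage factor MITF had 8 models on chromosome 3 and the longest locus of the 11 genes described here, at 228903 bp (start 69788586, end 70017488, plus strand). All 39 p53 target genes, all 49 genes of DNA replication, all 46 mitotic genes, all 56 replication-dependent histone genes and all 28 genes of the melanocyte lineage list were matched.

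Over all lists, 860 of 880 different entries were found. The unmatched entries included all 13 mitochondrially encoded respiratory chain genes and 6 small structured RNA genes, RN7SK among them.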

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

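Matching by the first symbol alone and the 200 bp limit were chosen after the table was seen. The plan had already set the 300 bp limit, for gene loci, and the older or newer symbols. With only the first symbol of each entry accepted, 848 of the listed genes were found instead of 860. With a span limit of 200 bp instead of 300 bp, 1776 transcript models fell under it instead of 1804. No paired analysis was possible because the value columns carry no replicate number or sample name. The alternatives that had been planned for the comparisons between groups (pseudocount, filter, scaling, retention of short genes, fit on the compared groups alone, minimum fold change, and omission of each library in turn) were not run, since no column of values was assigned to a sample. Depth per library was not determined, so no statement about the precision of expression values is made.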
